A study of Mus musculus with 9 samples.

How the data were processed

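Total RNA was taken from the ischemic hemisphere of male mice, with 3 libraries in each of 3 groups (sham, tMCAO, and tMCAO with celastrol). Per the labels' protocols, 5 µg of RNA per sample was depleted of ribosomal RNA with Ribo-Zero Gold, fragmented and converted to libraries with inserts near 300 bp, which were read as 2 × 150 bp on an Illumina NovaSeq instrument. Whether the library kit marked strand, and whether the counting used strand, is not given in the sources used here, so antisense and overlapping genes are reported as uncertain. Of 138 genes tested by name, 25 overlap another row of the table. Among them are Il1r2, Icam1, Mt2, Sult1a1, Sema5b and Agrp, whose levels are uncertain in the same way and are not marked again below.

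The authors deposited 1 table with 55385 gene rows, holding an estimated count and an FPKM value (fragments scaled for transcript length and library total) per gene and library. Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, edgeR and DESeq2 were used with the mm10 build; which settings were used is not given in the sources used here. Of the gene identifiers, 99.6% are in GENCODE M21, and 94.4% of these have the same end coordinate there, so coordinates are those of the deposited table. The deposited estimated counts are whole numbers. In genes with 1 transcript and 1 to 10 counts, at least 99.8% of them lay less than 1 above the value implied by the deposited FPKM, as estimates rounded up would. No per-sample column was left unmapped, and 0 rows named no gene. Where several rows shared a symbol (118 symbols), the row with the highest mean stood for the symbol.

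Totals ranged from 60392960 to 75158625 estimated counts per library (median 68726348). Ribosomal RNA genes took 0.633% to 0.776% of them and mitochondrial pseudogenes, which share sequence with mitochondrial genes, 1.50% to 1.96%. At this depth a count of 0 in a library is compatible with up to 3 counts, which covers counting error only. No 2 libraries differed by as little as sampling noise (chi-square per degree of freedom at least 83.0 for genes with at least 20 counts).

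Before the data were examined, the test had been written as limma on log2(FPKM + 0.5), with edgeR's quasi-likelihood test in its place should the table hold counts. Since it holds counts, edgeR was used, and limma on FPKM was kept as an alternative. Genes with an FPKM of at least 0.5 in at least 3 of the 9 libraries were kept, leaving 16982 genes: 13663 protein-coding, 1264 long non-coding, 1356 pseudogenes and 699 others, by the transcript types of the table. All 9 libraries entered 1 fit with 1 mean per group and TMM scaling (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest, two-sided), so the groups shared 1 estimate of the spread (common dispersion 0.0963, prior degrees of freedom 2.83). The installed default of the quasi-likelihood fit was kept as the main test after its newer form had also been run, and the newer form is given as an alternative. Adjusted p-values are Benjamini-Hochberg values over all genes tested with a threshold of 0.05, unless said to be adjusted over the list alone. Levels are CPM with SD, and log2 fold changes are given with a standard error (SE). For edgeR, whose test gives none, it is the fold change divided by the square root of the F statistic. It is approximate and least secure for genes near 0 in a group. Log2 CPM values for scores, principal components and correlations used a prior count of 2. Fold changes of single genes used edgeR's smaller default, which leaves those of genes at 0 uncertain, so for genes at 0 in a group a lower bound from a floor of 3 counts over the group is given.

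Gene lists for stress, inflammation, cell types and brain regions were fixed before the data were examined. Of these, 43 had at least 5 tested members and were tested with camera in limma 3.58.1 (preset correlation 0.01), with Benjamini-Hochberg adjustment over the lists. The lymphocyte list had 2 tested members and was not tested as a list. The filter on low values also left 8 of 16 neutrophil, 8 of 14 monocyte and 20 of 27 cytokine genes. It left 9 of 14 antigen presentation, 8 of 18 cell cycle, 8 of 16 histone and 5 of 8 erythrocyte genes. Shares and medians cover tested members only. Genes near 0 in sham could pass the filter only through the other groups, which favours rises against sham. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether a list's genes move one way on balance and does not compare the list with other genes. Scores per library are the mean over a list's members of the log2 CPM change from the sham mean. Some genes are in several lists.

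Genes were named by a rule fixed before the data were examined. It takes the genes past the threshold with groups that do not overlap, by size of change, and fills up by smallest unadjusted p, said not to pass, to 10 in each direction for tMCAO against sham and for celastrol against tMCAO and 5 for celastrol against sham. Predicted gene models were left out there. For lncRNAs the rule takes called genes, of which there were 0, and for each list described the 2 to 4 members with the smallest p. Genes said to lead a list do so by p, not by size of change. Genes named outside this rule (further list members, and the genes by which libraries are described in the last section) were chosen after their values were seen.

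The edgeR and DESeq2 tests and camera with the preset correlation were tested on simulated counts drawn from the real means and library sizes. In these, 50 genes were changed at each of 4 fold sizes and the complement list was raised. Genes were drawn independently of each other, and changes were set only in genes with enough counts. Other statistics, among them limma, voom, fry and camera with an estimated correlation, were not tested that way. Alternatives tried were other pseudocounts on the FPKM scale, other filters on low values, median-of-ratios and quantile scaling, a replicate block, voom library weights, a robust spread model, fits with only the 2 groups compared, and leaving out each library in turn. Limma on log2(FPKM + 0.5), written first, was run beside them. Added after the data had been seen were DESeq2 1.42.0, the newer edgeR fit, a thalamic marker score as a covariate, fry, and GENCODE M21 gene types for lncRNAs. Chance was gauged by refitting the 10 splits of each pair of groups, and the effect of shared tMCAO libraries by 20 simulations for correlations and 10 for counts. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.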

Results

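Ribosomal RNA-depleted total RNA of the ischemic brain hemisphere was sequenced in 9 libraries from male C57BL/6 mice aged 8 to 10 weeks, in 3 groups of 3 libraries. The sham group had the surgery without occlusion. In the tMCAO group (transient middle cerebral artery occlusion, a mouse model of ischemic stroke) a filament closed the artery for 90 min and was then withdrawn. The third group had the same occlusion and received celastrol, a plant triterpenoid, at 4.5 mg/kg into the peritoneum when reperfusion began. The time from reperfusion to sampling and the number of animals behind a library are not given in the sources used here, so p-values measure the spread between these libraries. Estimated counts summed to 72846548, 62794895 and 60392960 in sham replicates 1, 2 and 3, to 71716822, 70864412 and 61631210 in tMCAO, and to 68726348, 67252809 and 75158625 with celastrol. Mitochondrial genes took 5.80% to 7.39% of these counts. Xist lay at or below 0.334 CPM (counts scaled to the library total) and the Y-linked gene Ddx3y at or above 36.6 CPM in every library, for mice recorded as male. On the first principal component (31.0% of the variance) the sham libraries lay between −58.7 and −25.8 and the tMCAO libraries between 16.99 and 58.1. Celastrol replicates 1 and 3 lay at 44.1 and 20.3, and celastrol replicate 2 at −23.2.

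The first comparison, tMCAO against sham, asks what occlusion and reperfusion change in the hemisphere. Genes of reactive astrocytes, of cytokines and chemokines, of activated microglia and macrophages and of neutrophils were higher after tMCAO. Of 23 tested reactive astrocyte genes, 21 rose when adjusted over the list alone, with a median log2 fold change of 2.90. Of 20 cytokine and chemokine genes, 18 rose when adjusted over the list alone (median 4.51, also with the 4 genes absent from sham at their lower bound). Over all 16982 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of them. Serpina3n, an acute-phase protease inhibitor of reactive astrocytes, went from 20.02 ± 7.79 CPM (SD, n = 3) to 424 ± 187 CPM (SD, n = 3). Its log2 fold change was 4.40 ± 0.64 (SE), with an edgeR adjusted p of 0.00077 over the list alone and 0.0907 over all genes. Lcn2, which encodes the iron-carrier protein lipocalin 2, went from 2.85 ± 1.43 to 59.1 ± 42.5 CPM (SD, n = 3 each). The chemokine gene Ccl4 had 0 counts in the sham libraries and 637 in the tMCAO libraries, at least 191-fold higher when sham is set to a floor of 3 counts over the group. By the same floor the chemokine Ccl7 was at least 203-fold higher and the interleukin 1 receptor antagonist Il1rn at least 277-fold higher. In all 9 fits that left out 1 library, at least 21 reactive astrocyte genes and at least 16 cytokine genes rose.

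Members of other immune lists were higher too. Of 17 activated microglia and macrophage genes, 13 rose when adjusted over the list alone (median log2 fold change 1.67; 8 without sham replicate 3 or without tMCAO replicate 3). Among them were the scavenger receptor Msr1 (7.60 ± 1.22, SE) and the endotoxin co-receptor Cd14 (3.54 ± 0.65). Of 8 neutrophil markers tested, out of 16 in the list, 6 rose when adjusted over the list alone (median 3.26). Among them were the decoy receptor Il1r2 (2.92 ± 0.56) and S100a9 (3.38 ± 0.67), a calcium-binding protein of granulocytes. Of 14 complement genes, 10 rose when adjusted over the list alone (median 1.22), led by the anaphylatoxin receptor C5ar1 (3.15 ± 0.49) and C4b (2.35 ± 0.38). Of 15 NF-kappaB targets, 9 rose when adjusted over the list alone (median 0.84, or 0.52 without tMCAO replicate 1), and of 13 endothelial activation genes 8 rose when adjusted over the list alone (median 1.91). The adhesion molecule Icam1 (2.93 ± 0.44) is in both lists, and Lcn2 is in the reactive astrocyte, endothelial activation and glucocorticoid lists. The monocyte and infiltrating macrophage list had 2 members that rose among 8 when adjusted over the list alone, Chil3 (5.11 ± 0.98) and Arg1 (7.88 ± 2.09). This count was 1 without sham replicate 2 or 3 and 5 without tMCAO replicate 2. P2ry12, a purinergic receptor of resting microglia, fell from 21.5 ± 3.12 to 6.37 ± 0.63 CPM (SD, n = 3 each) and was the 1 of 14 homeostatic microglia markers that fell when adjusted over the list alone (adjusted p = 0.0021, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The count of such markers was 5 without tMCAO replicate 3 and 3 without celastrol replicate 2, which shares the estimate of the spread.

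Camera, a competitive list test with a preset correlation of 0.01, called each of these lists. For reactive astrocyte genes its adjusted p was 3.89e-41 (adjusted p = 0.134 with an estimated correlation) and for cytokines 4.17e-22 (adjusted p = 0.134 with an estimated correlation). The p with an estimated correlation was 0.149 for activated microglia, 0.149 for monocyte markers, 0.101 for neutrophil markers, 0.101 for complement, 0.134 for NF-kappaB targets and 0.134 for endothelial activation. The rotation test fry, which asks whether a list's members move one way on balance, called 6 lists in this comparison. These were reactive astrocyte genes, NF-kappaB targets, p53 genes and endothelial activation genes (adjusted p = 0.0387 each) and complement and neutrophil markers (adjusted p = 0.0304 each). Camera called 26 of 43 lists for the real groups and up to 28 when the same 6 libraries were regrouped. Interferon response genes were called higher by camera (median 0.80, or 0.51 without tMCAO replicate 3; adjusted p = 0.391 with an estimated correlation). Of 18 interferon genes, 3 rose when adjusted over the list alone, Ifitm3 (1.53 ± 0.36), Gbp2 (2.22 ± 0.63) and Ifit3 (1.37 ± 0.39). That count was 1 without sham replicate 1, 0 without sham replicate 2 or 3 or tMCAO replicate 1 or 3, and 9 without tMCAO replicate 2. Antigen presentation genes were called higher by camera (median 0.67; adjusted p = 0.311 with an estimated correlation), and 4 of 9 rose when adjusted over the list alone, led by H2-D1 (0.91 ± 0.24) and Tap1 (1.45 ± 0.39). That count was 2 without sham replicate 1 or celastrol replicate 3 and 0 without sham replicate 2 or 3 or tMCAO replicate 1 or 3. The inflammasome, necroptosis and ferroptosis list was called higher by camera (median 0.81; adjusted p = 0.193 with an estimated correlation). Its member Alox5ap (1.08 ± 0.23), needed for leukotriene synthesis, rose when adjusted over the list alone, and none of that list did so without sham replicate 3. The count was 2 without sham replicate 2, tMCAO replicate 2 or 3 or celastrol replicate 1, and 5 without celastrol replicate 2. Tap1 and Alox5ap each overlap a gene on the other strand, and the counting is not stated to use strand.

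**Figure D1:**
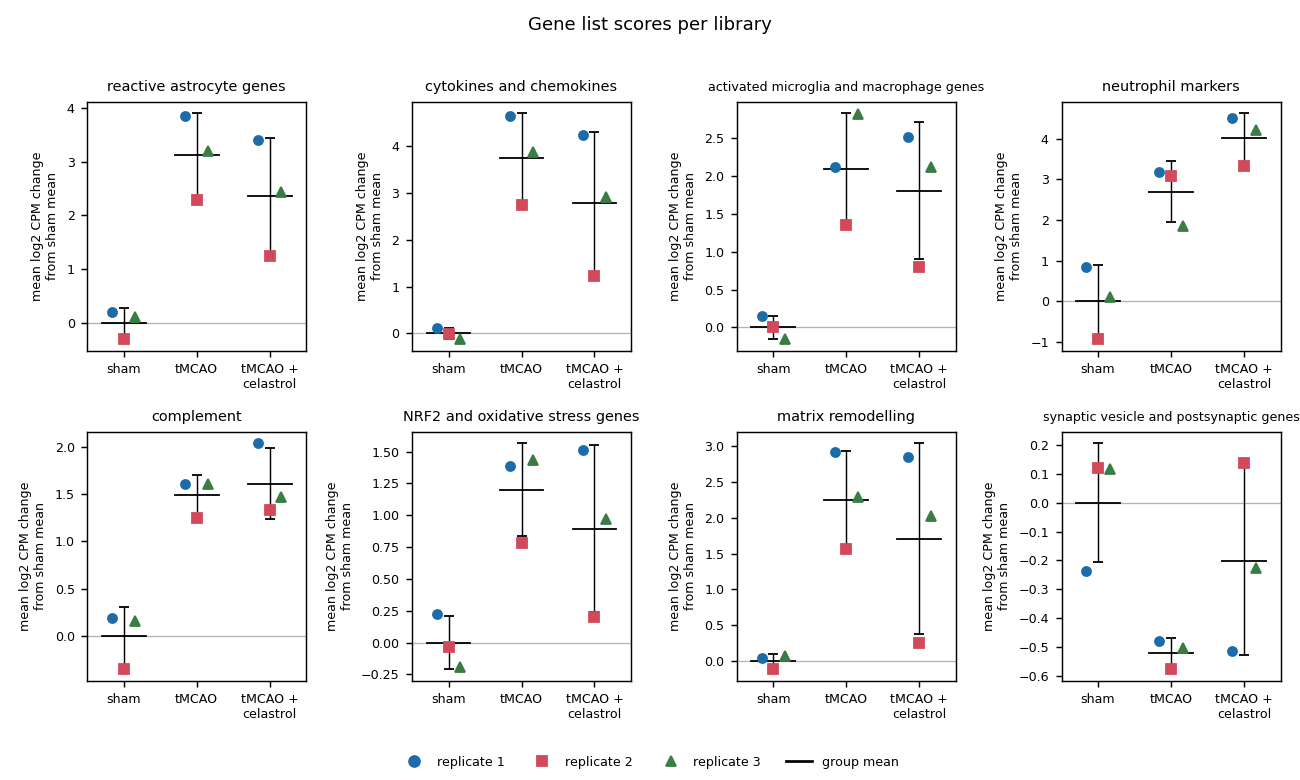
Each panel plots, for 1 gene list, the mean log2 CPM change of its tested members from the sham mean in each of the 9 libraries (points), with the group mean and SD as lines. The reactive astrocyte score lay between −0.31 and 0.20 in sham, between 2.29 and 3.86 after tMCAO, and at 3.42, 1.24 and 2.44 in celastrol replicates 1, 2 and 3.

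Oxidative stress, matrix and cell death genes were also higher after tMCAO. Of 17 NRF2 and oxidative stress genes, 14 rose when adjusted over the list alone and 0 over all genes tested (median log2 fold change 0.90; camera adjusted p = 3.93e-13, adjusted p = 0.167 with an estimated correlation). The heme-degrading enzyme Hmox1 went from 5.05 ± 0.50 to 103 ± 72.1 CPM, and the metallothionein Mt2 from 52.6 ± 23.3 to 313 ± 153 CPM (SD, n = 3 each). The NRF2 count was 4 without sham replicate 2, 5 without sham replicate 3, 4 without tMCAO replicate 1, 5 without tMCAO replicate 3 and 9 without celastrol replicate 3. Of 16 matrix remodelling genes, 10 rose when adjusted over the list alone (median 2.28; adjusted p = 0.167 with an estimated correlation), among them the proteases Adamts1 (2.89 ± 0.57) and Adamts9 (2.79 ± 0.62). The matrix count was 5 without sham replicate 2 and 6 without sham replicate 1, sham replicate 3 or tMCAO replicate 1. The protease inhibitor Timp1 had a log2 fold change of 5.32 ± 1.09 and lies within the abundant neuronal gene Syn1 on the other strand. Of 16 p53 and apoptosis genes, 6 rose when adjusted over the list alone (median 0.60; adjusted p = 0.134 with an estimated correlation), led by the cell cycle inhibitor Cdkn1a (2.38 ± 0.42) and Tnfrsf12a (2.53 ± 0.52). That count was 2 without sham replicate 2, sham replicate 3 or tMCAO replicate 1. Of 13 glucocorticoid response genes, 3 rose when adjusted over the list alone (median 0.77; adjusted p = 0.176 with an estimated correlation), and this count was 6 without sham replicate 1 and 9 without tMCAO replicate 3. They were Lcn2 (4.37 ± 0.57), Cdkn1a and the co-chaperone gene Fkbp5, which went from 49.6 ± 22.0 to 122 ± 48.1 CPM (SD, n = 3 each).

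Immediate early genes split. Of 22 such genes, 4 rose when adjusted over the list alone, Atf3 (4.17 ± 0.86), Ier3 (1.42 ± 0.37), Fosl1 (3.97 ± 1.24) and Jun (50.2 ± 7.73 CPM in sham, 100.4 ± 16.5 CPM after tMCAO, SD, n = 3 each), and Homer1 (−1.49 ± 0.47), a postsynaptic scaffold gene, fell. The list median was −0.65 and camera did not call the list (adjusted p = 0.174). With 1 library left out, the median ran from −0.89 to −0.37 and the list was called lower in 3 of 9 fits. The 4 genes that rose became 0 without sham replicate 2, sham replicate 3 or tMCAO replicate 1, 1 without tMCAO replicate 2 and 2 without celastrol replicate 1. Homer1 or other members that fell numbered 6 without sham replicate 1, 3 without celastrol replicate 2, 7 without celastrol replicate 3 and 0 in the other 6 such fits. Heat shock chaperones were not called by camera (median 0.18, adjusted p = 0.125). With 1 library left out, their median ran from −0.01 to 0.30 and the list was called in 3 of 9 fits. The small chaperone Hspb1 (3.57 ± 0.77) and the co-chaperone Bag3 (1.52 ± 0.41) rose when adjusted over the list alone. This count of 2 was 0 without any 1 sham library or tMCAO replicate 1, 1 without tMCAO replicate 3 or celastrol replicate 3, and 4 without celastrol replicate 1 or 2. The hypoxia and glycolysis list was not called (median 0.06; camera adjusted p = 0.177), and its members Hk2 (1.71 ± 0.35) and Adm (1.89 ± 0.44) rose when adjusted over the list alone. Without sham replicate 2 or tMCAO replicate 1 this count was 0, and without tMCAO replicate 2 it was 1. The stress phosphatase subunit gene Ppp1r15a (1.31 ± 0.32) rose when adjusted over the list alone, but not without any 1 sham or tMCAO library or celastrol replicate 3, and the count was 2 without celastrol replicate 2. Its list, endoplasmic reticulum stress genes, had a median of 0.07 (camera adjusted p = 0.273), cell cycle genes 0.51 (0.120) and clock genes −0.11 (0.262). Camera called the 30 cytosolic ribosomal protein genes higher (median 0.30, all 30 positive; adjusted p = 0.361 with an estimated correlation) and cholesterol synthesis genes higher (median 0.36; adjusted p = 0.508 with an estimated correlation; not called without tMCAO replicate 1, at a median of 0.12). It called mitochondrially encoded genes lower (median −0.22; adjusted p = 0.460 with an estimated correlation), a direction that turned under quantile normalization. Replication-dependent histone genes were called lower (median −0.27; adjusted p = 0.391 with an estimated correlation), a call lost in 6 of the 9 fits that left out 1 library, namely those without sham replicate 1, tMCAO replicate 1 or 2, or any celastrol replicate. It was also lost with no filter, with an FPKM of at least 1, with the replicate block and with voom weights. Fits with only the 2 groups compared or with the thalamic covariate lost it as well. Of the histone genes, H4c14 (−1.50 ± 0.30) fell when adjusted over the list alone, joined by 1 more without tMCAO replicate 3.

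Neuronal genes lay lower after tMCAO. Camera called synaptic vesicle and postsynaptic genes lower (median log2 fold change −0.46, 19 of 20 negative; adjusted p = 0.215 with an estimated correlation), as it did glutamate and GABA receptors (median −0.38, 22 of 24 negative; adjusted p = 0.311 with an estimated correlation). Excitatory neuron markers (median −0.52; adjusted p = 0.231 with an estimated correlation) and inhibitory neuron markers (median −0.11; adjusted p = 0.215 with an estimated correlation) were called lower as well, the latter not without tMCAO replicate 2. Without sham replicate 1, 2 or 3 the inhibitory median was −0.25, −0.20 and −0.18, and without tMCAO replicate 1, 2 or 3 it was −0.24, −0.03 and −0.32. When adjusted over the list alone, the postsynaptic scaffold genes Shank3 and Shank1 fell (2 of 20 synaptic genes; edgeR found 0 over all genes). Shank3 went from 171 ± 25.5 to 82.8 ± 9.90 CPM (SD, n = 3 each). The count of synaptic genes that fell was 1 without sham replicate 2 or tMCAO replicate 2, 8 without sham replicate 1 or celastrol replicate 1, 13 without celastrol replicate 2 and 4 without celastrol replicate 3. Of 13 inhibitory neuron markers, 3 fell when adjusted over the list alone, Vip (−1.10 ± 0.26), Cck (−0.96 ± 0.27) and the transcription factor gene Dlx1 (−0.99 ± 0.29), which overlaps an antisense gene. Their count was 0 without sham replicate 2, tMCAO replicate 2 or celastrol replicate 1, and 1 without sham replicate 3 or tMCAO replicate 1. Of 24 receptor genes and of 13 excitatory markers, 0 passed when adjusted over the list alone. Homeostatic microglia markers were called lower by camera (median −0.61, or −0.28, −0.33 and −0.33 without sham replicate 2, tMCAO replicate 1 and tMCAO replicate 2; adjusted p = 0.391 with an estimated correlation).

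Lists of other cell types and regions varied between libraries as well as groups. Camera did not call markers of striatal projection neurons (median −0.56), hippocampus (0.55), thalamus (0.66), astrocytes (−0.05), oligodendrocytes (0.03), oligodendrocyte precursors (0.05), endothelium (0.21), pericytes and fibroblasts (0.49), ependyma (0.64) or erythrocytes (0.21), nor known long non-coding RNAs (−0.00; mean 0.24). With 1 library left out, the striatal median ran from −1.61 to 0.30, the hippocampal from −0.33 to 1.42 and the thalamic from −0.34 to 1.18. Striatal and endothelial markers were called in 3 of these 9 fits. Astrocyte, pericyte, ependymal and erythrocyte markers were called in 2, thalamic markers in 1 and the other lists named here in 0. For oligodendrocytes and precursors the median was positive and the direction of the test negative. Within them, Ugt8a (−1.07 ± 0.23), an enzyme of myelin lipid synthesis, and the pericyte gene Rgs5 (−0.35 ± 0.08) fell when adjusted over the list alone. Ugt8a was not called without sham replicate 1, sham replicate 3 or tMCAO replicate 1, nor Rgs5 without any 1 sham library, tMCAO replicate 1 or celastrol replicate 3. Choroid plexus markers were called higher (median 2.04; adjusted p = 0.485 with an estimated correlation), but not without tMCAO replicate 2. Hypothalamic markers were called higher (median 2.43; adjusted p = 0.485 with an estimated correlation), but not without sham replicate 2 or without tMCAO replicate 1 (median 0.20). Neither list was called with pseudocount 0.1 or 1, with an FPKM of at least 1 or with limma on log2(FPKM + 0.5), nor was the choroid list with voom library weights. The hypothalamic score was 3.64 in tMCAO replicate 1 and 0.38 and 0.76 in the other tMCAO libraries, and the thalamic score was 2.06 in tMCAO replicate 2, −0.52 and −0.12 in the others. The glial, cytokine and neuronal lists above were compared across libraries that differed in these region scores.

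**Figure D2:**
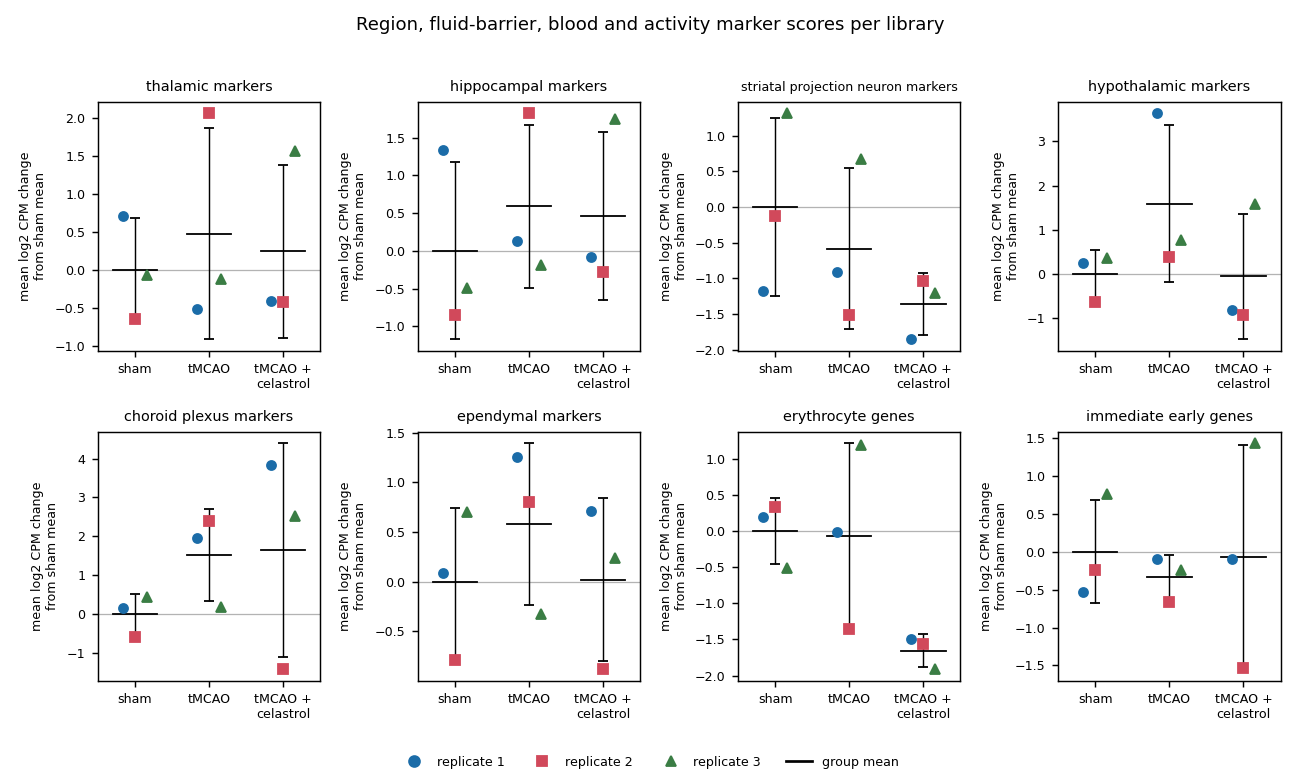
Points are the 9 libraries and the vertical axis is the mean log2 CPM change of a list's tested members from the sham mean, with group means and SDs as lines. Choroid plexus scores ran from −1.43 to 3.84 among the celastrol libraries, and all 3 erythrocyte scores of that group lay at or below −1.49.

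Gene by gene, tMCAO against sham gave 0 calls in 16982 genes with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment; the lowest adjusted p was 0.0763. At an unadjusted p under 0.05 there were 2534 genes, 1454 higher and 1080 lower, where 849 are expected by chance. DESeq2 called 836 genes, 557 higher and 279 lower, and each of them had an unadjusted edgeR p under 0.05 in the same direction. On simulated counts for this comparison, edgeR recovered 32% of genes changed 2-fold and 96% of those changed 8-fold. It called 10 of 16768 unchanged genes where DESeq2 called 72. Of the 50 genes changed at each of 2-, 4-, 8- and 16-fold, DESeq2 recovered 25, 42, 49 and 49. False calls were thus well over 5% of its calls, and its counts for the real libraries may hold many. The simulated genes varied independently of each other, and changes were set only in genes with enough counts. These recovered shares may therefore be too high for the real libraries. The 3 libraries of one group lay apart from the 3 of the other for 23.5% of genes, against 10% by chance. Without celastrol replicate 2, which enters only through the shared estimate of the spread, edgeR called 91 genes, 81 higher and 10 lower. Without sham replicate 1 it called 13, without sham replicate 3 or tMCAO replicate 2 it called 2, and without celastrol replicate 1 it called 1. With only the sham and tMCAO libraries in the fit it called 29, and with voom library weights 14.

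The genes with the smallest unadjusted p did not pass (edgeR adjusted p from 0.0763 to 0.102). Fcgr4, an activating receptor for immunoglobulin G on myeloid cells (mm10 chromosome 1, 171018920 to 171029761), was at 0.198 ± 0.027 CPM in sham and 2.85 ± 0.98 CPM after tMCAO (SD, n = 3 each; adjusted p = 0.0763). Other genes of immune cell surface receptors were Cd244a (log2 fold change 6.97 ± 0.87), Cd300lf (4.55 ± 0.58), Ms4a6d (3.85 ± 0.51), Ms4a6c (2.88 ± 0.40) and Gpr84 (3.12 ± 0.44), with Lcn2 (4.37 ± 0.57), Serpina3n and Ccl4 beside them. Cd244a was at 0.023 ± 0.040 CPM in sham and 2.94 ± 1.03 CPM after tMCAO (SD, n = 3 each). So near 0 in sham, its fold change is uncertain. The lncRNA gene BE692007 (2.59 ± 0.37; chromosome 19, 11470166 to 11484578) lies antisense over Ms4a6c, so the reads given to each are uncertain, and Cd244a and Cd300lf also overlap a gene on the other strand. On the lower side, Arrb1, which encodes the receptor-desensitizing protein beta-arrestin 1 (chromosome 7, 99535466 to 99606771), was at 279 ± 41.0 CPM in sham and 67.1 ± 15.8 CPM after tMCAO (SD, n = 3 each; adjusted p = 0.0907). The transcription factor gene Bach2 was at 12.8 ± 1.12 and 2.13 ± 0.56 CPM, and Etv5 at 167 ± 32.7 and 66.7 ± 14.2 CPM. The rest of the 10 on this side were Mical2 (−1.02 ± 0.14), Acbd5 (−0.82 ± 0.12), P2ry12 (−1.76 ± 0.28; overlapping Med12l), Shank3 (−1.05 ± 0.17), Ephb1 (−0.79 ± 0.13), Hivep1 (−0.68 ± 0.12) and Fxyd7 (35.5 ± 3.78 and 17.8 ± 1.47 CPM).

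**Figure D3:**
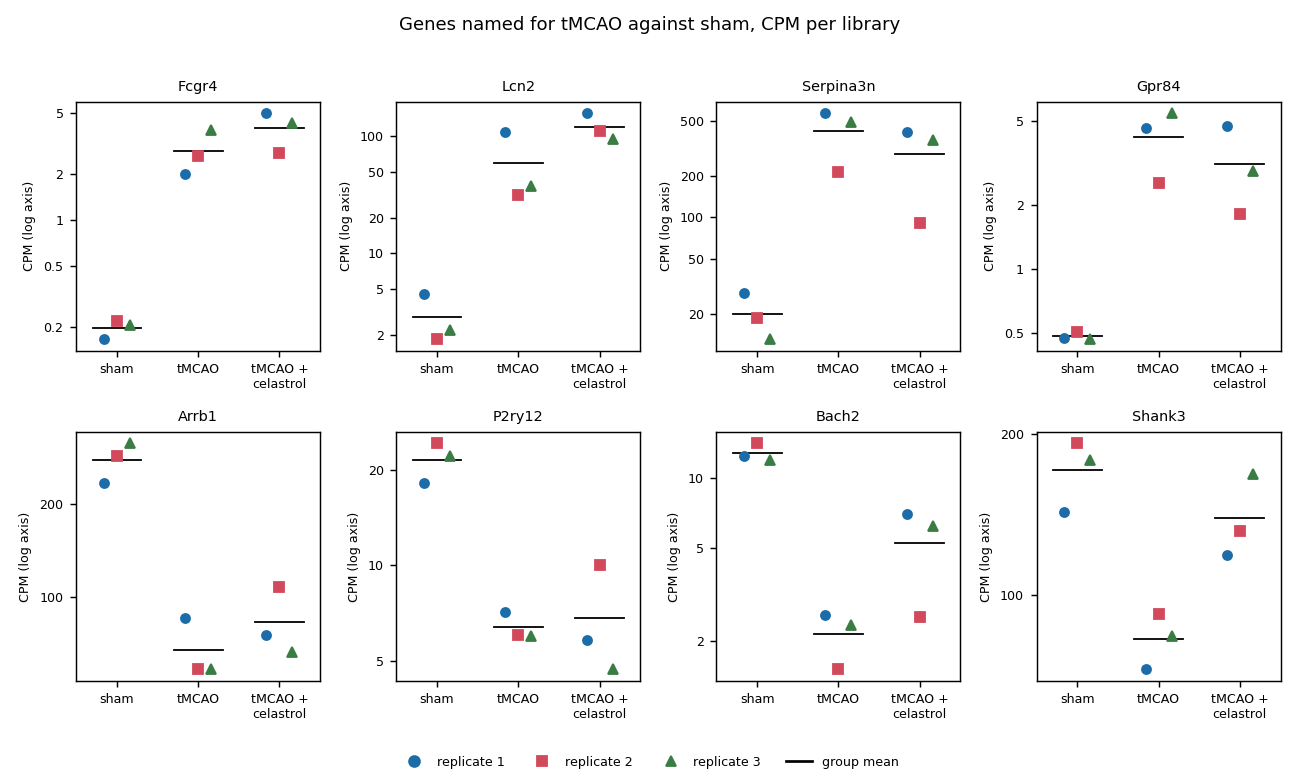
CPM on a log axis for 8 genes in each of the 9 libraries (points), with horizontal lines at the group means. Fcgr4 was at or below 0.219 CPM in the sham libraries and at or above 2.00 CPM in the other 6.

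Among 1264 lncRNA genes tested, edgeR called 0 in tMCAO against sham (lowest adjusted p 0.0907, Benjamini-Hochberg), also when adjusted over the lncRNAs alone. At an unadjusted p under 0.05 there were 146, 71 higher and 75 lower, with 63.2 expected by chance, and DESeq2 called 47, 25 higher and 22 lower. Without sham replicate 1 edgeR called 2, and without celastrol replicate 2 it called 1. Of 40 tested lncRNAs known by name, 0 passed when adjusted over the list alone. Those with the smallest p were hosts of small nucleolar RNAs: Gas5 (0.73 ± 0.16; 55.7 ± 4.57 CPM in sham and 92.6 ± 4.98 CPM after tMCAO, SD, n = 3 each), Snhg15 (1.46 ± 0.38), Zfas1 (0.76 ± 0.21) and Snhg1 (1.09 ± 0.34). Gas5 and Zfas1 overlap genes on the other strand. For celastrol against tMCAO, 0 lncRNA genes were called by edgeR and 0 by DESeq2, with 48 at an unadjusted p under 0.05 and 63.2 expected.

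Celastrol against tMCAO asks what the drug changes in the injured hemisphere. Erythrocyte genes were lower with celastrol, and cholesterol synthesis and interferon response genes lay lower as lists. All 5 tested erythrocyte genes fell when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.0077 for the 4 globin genes) and 0 over all genes tested, with a median log2 fold change of −1.86, or −1.10 without tMCAO replicate 3. The beta-globin gene Hbb-bs was at 97.6 ± 29.9 CPM in sham, 109 ± 79.3 CPM after tMCAO and 30.2 ± 5.11 CPM with celastrol (SD, n = 3 each). Camera called the list lower (adjusted p = 4.35e-11; adjusted p = 0.611 with an estimated correlation). The heme synthesis gene Alas2, which overlaps Apex2 on the other strand, had a log2 fold change of −2.01 ± 0.66 (SE), or −1.10 ± 0.55 without tMCAO replicate 3. Globin genes have near-identical copies, so the split between them is uncertain. The estimated correlation between the 5 genes was 0.988, so they are close to 1 measurement rather than 5. Fry did not call the list (adjusted p = 0.677). In tMCAO replicates 1, 2 and 3 Hbb-bs was at 92.5, 39.5 and 195 CPM, so replicate 2 also lay below the sham libraries.

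All 18 cholesterol synthesis genes had negative fold changes with celastrol against tMCAO (median −0.39, or −0.10 without tMCAO replicate 1), led by Idi1 (−0.81 ± 0.23) and Nsdhl (−0.57 ± 0.21), and 0 passed when adjusted over the list alone. Of 18 interferon response genes, 17 were negative (median −0.60), with Usp18 at −1.44 ± 0.47 and Ifit3 at −0.98 ± 0.39, and again 0 passed when adjusted over the list alone. Camera called both lists lower (adjusted p = 9.84e-08 and 6.46e-06; adjusted p = 0.611 with an estimated correlation for each). The interferon median was −0.29 without tMCAO replicate 3, and −1.18, −0.37 and −0.33 without celastrol replicate 1, 2 and 3. With the erythrocyte genes these were the 3 of 22 called lists that were called in all 9 fits leaving out 1 library. In the tMCAO group the cholesterol score was 0.78 in replicate 1 and 0.11 and 0.06 in the others, and the interferon score was 0.997, −0.043 and 1.21. With celastrol the cholesterol scores were −0.023, −0.057 and −0.022 in replicates 1, 2 and 3. The interferon scores there were 0.848, −0.264 and −0.283, so the 2 groups overlapped for that list.

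Lists of injury genes were called in both directions with celastrol against tMCAO. Cytokines and chemokines (median −0.59, 16 of 20 negative; adjusted p = 0.611 with an estimated correlation) and reactive astrocyte genes (median −0.62, 18 of 23 negative; adjusted p = 0.611 with an estimated correlation) were called lower by camera. Synaptic vesicle and postsynaptic genes (median 0.29, 19 of 20 positive; adjusted p = 0.611 with an estimated correlation) were called higher. Without celastrol replicate 2 none of these 3 lists was called, at medians of −0.20, −0.19 and 0.04 (reactive astrocyte genes also not without tMCAO replicate 1, at −0.41). Without celastrol replicate 1 the median was −1.66 for cytokines and −1.16 for astrocyte genes, and that of cytokines was −0.37 and −0.97 without tMCAO replicate 1 and 2. Cytokine scores were 4.24, 1.23 and 2.91 in celastrol replicates 1, 2 and 3 and 4.64, 2.74 and 3.87 in tMCAO. When adjusted over the list alone, 0 cytokine and 0 astrocyte genes passed, while Shank3 rose, from 82.8 ± 9.90 to 139 ± 25.6 CPM (SD, n = 3 each; edgeR adjusted p = 0.0321 over the list alone and 0.976 over all genes). That call was lost without sham replicate 3, without any 1 tMCAO library and without celastrol replicate 2 or 3. Glucocorticoid response genes were called higher (median 0.40; adjusted p = 0.611 with an estimated correlation; not called without tMCAO replicate 3, at a median of 0.16), with Tsc22d3 at 0.57 ± 0.19 and Sult1a1 at 0.95 ± 0.32. Neutrophil markers (median 0.63, or 1.07 without tMCAO replicate 1; adjusted p = 0.611 with an estimated correlation) were called higher, but not without tMCAO replicate 3 or celastrol replicate 1 or 3. Ngp, a protein of neutrophil granules, was at 0.229 ± 0.308 CPM after tMCAO and 4.43 ± 2.32 CPM with celastrol (SD, n = 3 each; edgeR adjusted p = 0.0872 over the list alone). Heat shock chaperones were called higher (median 0.28, or 0.15 without tMCAO replicate 1; adjusted p = 0.611 with an estimated correlation; not called without celastrol replicate 1, at a median of 0.09, or celastrol replicate 3).

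Region lists differed between these groups too. Markers of striatal projection neurons (median −1.02, all 15 negative; adjusted p = 0.611 with an estimated correlation) were called lower, but not without tMCAO replicate 3 (median 0.03). Hypothalamic markers (median −1.66, or −3.02 without celastrol replicate 3; adjusted p = 0.611 with an estimated correlation) were called lower, but not without tMCAO replicate 1 (median −0.02). Camera also called NF-kappaB, NRF2, antigen presentation, cell cycle, ribosomal protein and ependymal lists lower. It called immediate early, clock, receptor, histone and astrocyte lists higher. Each of these 11 calls was lost without at least 1 library, and the lowest adjusted p of any list in this comparison was 0.611 with an estimated correlation. For fry the lowest was 0.677. The ribosomal protein list, at a median of −0.13 (−0.20 without celastrol replicate 1), was lost without tMCAO replicate 3 (−0.05) or celastrol replicate 2 (−0.04), and immediate early genes (median 0.74, or 1.15 without celastrol replicate 2) without tMCAO replicate 2 or 3 or celastrol replicate 3 (−0.16) and under quantile normalization. Without celastrol replicate 3 the test of immediate early genes pointed down, and without celastrol replicate 2 those of NRF2 genes and of receptors turned as well. When the same 6 libraries were regrouped, camera called up to 30 lists. The remaining lists were not called, among them complement (median 0.15), activated microglia (−0.16), matrix remodelling (−0.24), p53 genes (−0.18), endothelial activation (0.37) and known lncRNAs (0.04). With 1 library left out, the median ran from −0.45 to 0.19 for activated microglia and from −0.55 to 0.115 for matrix remodelling. It ran from 0.005 to 0.33 for complement, −0.36 to 0.03 for p53 genes and 0.10 to 0.55 for endothelial activation. The endothelial activation list was called in 4 of these 9 fits, p53 genes in 1, and complement, activated microglia and matrix remodelling in 2 each.

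By gene, celastrol against tMCAO gave 0 calls in 16982 genes with edgeR's quasi-likelihood test (lowest Benjamini-Hochberg adjusted p 0.976). At an unadjusted p under 0.05 there were 698 genes, 382 higher and 316 lower, with 849 expected by chance. The groups did not overlap for 7.86% of genes, against 10% by chance. DESeq2 called 18 genes, 11 higher and 7 lower. On simulated counts for this comparison edgeR recovered 42% of genes changed 2-fold and 82% of those changed 4-fold, and DESeq2 called 57 of 16768 unchanged genes. Of the 50 genes changed at each of 2-, 4-, 8- and 16-fold, DESeq2 recovered 32, 43, 47 and 50. Well over 5% of its calls were false there too. The limits of the simulated counts given for tMCAO against sham apply here too. Without tMCAO replicate 2 edgeR called 2 genes.

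None of the genes with the smallest p passed over all genes (edgeR adjusted p = 0.976 for each, Benjamini-Hochberg). Cx3cl1, which encodes the neuronal chemokine fractalkine (chromosome 8, 94772009 to 94782427), was at 52.9 ± 12.96 CPM after tMCAO and 534 ± 185 CPM with celastrol (SD, n = 3 each). Sham libraries ranged from 128 to 930 CPM. The transcription factor gene Lhx2 was at 44.8 ± 1.64, 22.4 ± 4.58 and 43.7 ± 11.2 CPM in sham, tMCAO and celastrol (SD, n = 3 each). Prelp, which encodes a matrix proteoglycan, was at 19.7 ± 5.03, 11.8 ± 1.42 and 25.0 ± 2.33 CPM. Also on the higher side were Alkbh4 (1.83 ± 0.36 and 4.51 ± 0.53 CPM), Arhgef3 (0.68 ± 0.14), the pseudogene Atp6v0c-ps2 (3.65 ± 0.78), Tmem178 (0.80 ± 0.17), Shank3, the calcium channel subunit gene Cacna2d1 (0.84 ± 0.19) and Kirrel2 (1.69 ± 0.38). On the lower side, Fam102b (chromosome 3, 108970997 to 109027607) was at 55.3 ± 14.8, 55.0 ± 23.3 and 12.5 ± 0.343 CPM in sham, tMCAO and celastrol (SD, n = 3 each). Cirbp, which encodes a cold-inducible RNA-binding protein, was at 30.6 ± 3.54, 66.0 ± 19.2 and 35.0 ± 2.80 CPM. The transporter gene Slc26a10 was at 2.67 ± 0.95, 11.2 ± 2.38 and 3.41 ± 0.65 CPM but overlaps B4galnt1, and Tmem8b (−1.10 ± 0.19) overlaps Fam221b. The others were Hmgn2 (−0.61 ± 0.11), Fip1l1 (−0.84 ± 0.17), Gpr83 (−1.05 ± 0.24), Gemin4 (−0.63 ± 0.15), Rtl9 (−1.21 ± 0.29) and Evpl (−1.03 ± 0.26). Fip1l1 and Gemin4 overlap other genes.

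**Figure D4:**
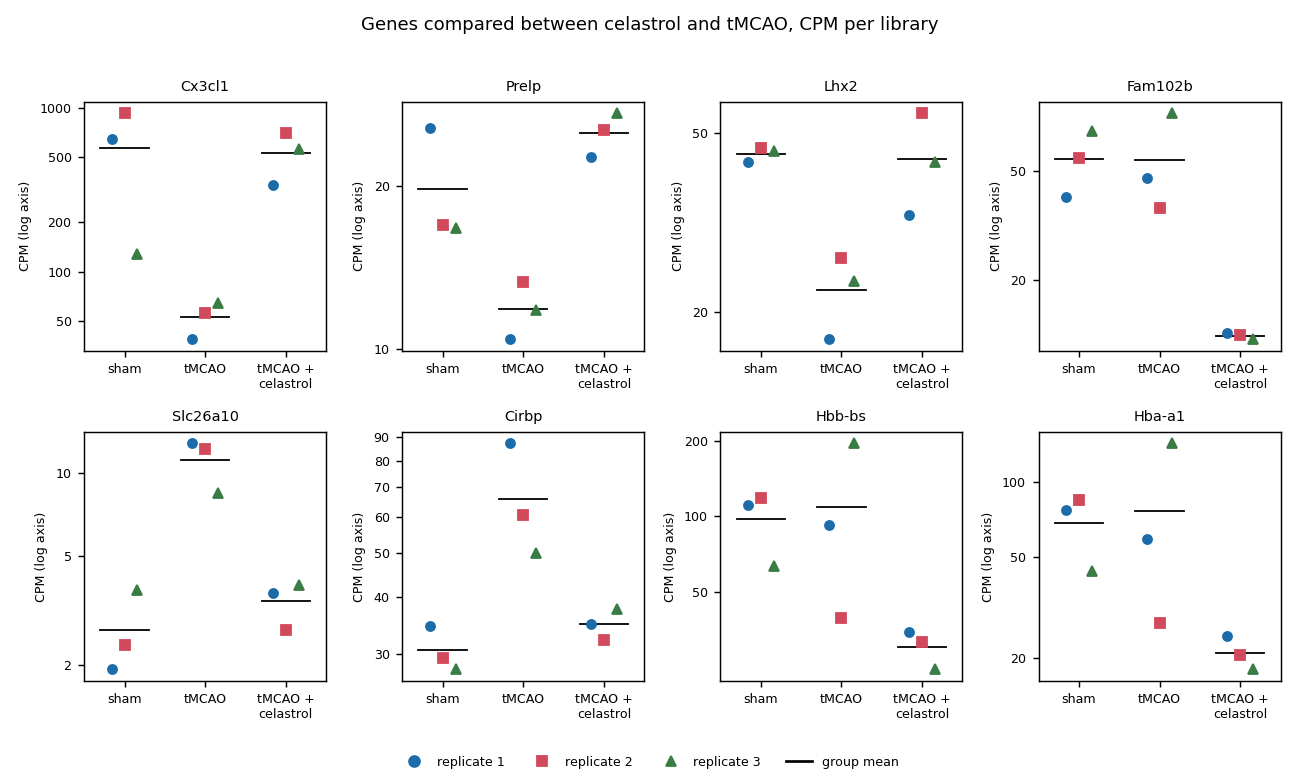
CPM on a log axis for 8 genes in each of the 9 libraries (points), with horizontal lines at the group means. Fam102b averaged 12.5 CPM with celastrol and at least 55.0 CPM in each of the other groups, and Cx3cl1 was at 128 CPM in sham replicate 3 but at 645 and 930 CPM in the other sham libraries.

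Whether celastrol moved genes against their change after tMCAO was counted directly. With edgeR and adjusted p, 0 genes were called in both comparisons with opposite signs and 0 with the same sign, and DESeq2 gave 12 opposite. Without tMCAO replicate 2 edgeR gave 2. At an unadjusted p under 0.05, 322 genes had opposite signs and 4 the same sign, and 7 of the 19 other ways to assign the tMCAO and celastrol libraries gave more opposite genes, up to 1202. The tMCAO libraries stand in both comparisons, and simulated celastrol libraries equal to tMCAO gave 271 and 46.9 on average, while independent lists would give 51.3 and 52.8. Across genes, which are not independent replicates, the fold changes correlated at −0.48, against −0.28 ± 0.017 (SD of 20 simulations) in simulations without a drug effect. Those simulations started from fitted group means, which already hold noise, and drew genes independently of each other. They are therefore no exact reference, and their SD covers simulation error only. The covariance was −0.130 against −0.0894, a difference of −0.0406. Of 20 ways to assign the libraries, 5 gave a correlation as negative. The 3 tMCAO libraries are too few to split between the comparisons, so part or all of the excess may come from sharing them.

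Celastrol against sham asks what differed from sham after occlusion with celastrol. Complement and neutrophil lists were higher, as were glucocorticoid response and endothelial activation genes. Of 14 complement genes, 12 rose when adjusted over the list alone (median log2 fold change 1.29), and of 8 neutrophil markers 7 rose when adjusted over the list alone (median 4.08). Both lists were called by camera with the preset and with an estimated correlation (adjusted p = 0.0158 each) and by fry (adjusted p = 0.0112 each). C5ar1 (4.05 ± 0.51), Il1r2 (3.55 ± 0.57) and S100a9 (4.01 ± 0.69) were among the members that rose. Of 13 glucocorticoid response genes, 12 rose when adjusted over the list alone (median 1.18; adjusted p = 0.0586 with an estimated correlation; fry adjusted p = 0.0311), and 6 without sham replicate 2 or celastrol replicate 1 or 3. Lcn2 (5.40 ± 0.60), Pdk4 (1.22 ± 0.24) and Sult1a1 (1.49 ± 0.32) were among them. Of 13 endothelial activation genes, 10 rose when adjusted over the list alone (median 2.28; adjusted p = 0.0586 with an estimated correlation; fry adjusted p = 0.0311), among them P-selectin, Selp (4.73 ± 0.82).

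In the same comparison, 19 of 23 reactive astrocyte genes (median 2.36; adjusted p = 0.0909 with an estimated correlation), 13 of 20 cytokines (median 3.37, or 1.899 without celastrol replicate 1; 0.136 with an estimated correlation) and 13 of 17 activated microglia genes (median 1.49; adjusted p = 0.121 with an estimated correlation) rose when adjusted over the list alone. The cytokine count was 7 without sham replicate 3 or celastrol replicate 1. The microglia count was 8 without sham replicate 1, 7 without sham replicate 2 or 3 and 8 without celastrol replicate 1. Heat shock chaperones were called higher (median 0.44, or 0.19 and 0.69 without celastrol replicate 1 and 2; adjusted p = 0.314 with an estimated correlation), and 4 of 17 rose when adjusted over the list alone, Hspa1b (3.54 ± 0.84), Hspa1a (3.28 ± 0.88), Hspb1 (2.94 ± 0.75) and Bag3 (1.44 ± 0.41). That count was 0 without any 1 sham library or celastrol replicate 1 or 3, and 8 without celastrol replicate 2. Hspa1a and Hspa1b are near-identical copies. Choroid plexus markers were called higher (median 3.05, or 1.59 without celastrol replicate 1; adjusted p = 0.356 with an estimated correlation), and 5 of 11 rose when adjusted over the list alone, F5 (3.61 ± 1.04) and Aqp1 (3.05 ± 0.93) among them. The choroid count was 0 without any 1 sham library or celastrol replicate 1, 8 without tMCAO replicate 3, 10 without celastrol replicate 2 and 3 without celastrol replicate 3. All 5 erythrocyte genes fell when adjusted over the list alone (median −1.69, camera adjusted p = 0.136 with an estimated correlation). That correlation was 0.985, so the 5 are close to 1 measurement here too. Striatal projection neuron markers were called lower (median −1.68, or −0.65 without sham replicate 3; adjusted p = 0.328 with an estimated correlation), as was the homeostatic microglia list (median −0.30, or −0.45 without celastrol replicate 2; adjusted p = 0.407 with an estimated correlation).

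By gene, celastrol against sham gave 1 call over all genes. Fcgr4 rose from 0.198 ± 0.027 to 4.01 ± 1.16 CPM (SD, n = 3 each), a log2 fold change of 4.34 ± 0.39 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0323). Its adjusted p was 0.0559 without sham replicate 1, 0.196 without sham replicate 2, 0.220 without sham replicate 3, 0.0673 without tMCAO replicate 2, and 0.159 and 0.104 without celastrol replicate 1 and 3. It was 0.0955 with pseudocount 1 in limma, 0.0515 with limma on log2(FPKM + 0.5) and 0.0779 with a thalamic marker score as a covariate. At an unadjusted p under 0.05 there were 1445 genes, 967 higher and 478 lower, and the groups did not overlap for 13.4% of genes against 10% by chance. DESeq2 called 380 genes, 314 higher and 66 lower. Without celastrol replicate 2 edgeR called 46 genes, without tMCAO replicate 3 it called 7, without sham replicate 1 or tMCAO replicate 1 it called 3, and without sham replicate 2 or 3, tMCAO replicate 2 or celastrol replicate 1 or 3 it called 0. The next genes by p on the higher side were Ms4a6c (3.97 ± 0.42), Lcn2, Cd244a (7.10 ± 0.87) and Tma16 (1.53 ± 0.19), with edgeR adjusted p from 0.0529 to 0.0638. The fold change of Cd244a is uncertain, since its sham level was 0.023 ± 0.040 CPM (SD, n = 3). On the lower side were Arrb1 (−1.75 ± 0.23), Fam102b (−2.14 ± 0.30), P2ry12 (−1.66 ± 0.28), Sema5b (−1.39 ± 0.24) and Ephb1 (−0.73 ± 0.13), with adjusted p from 0.0678 to 0.137.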

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

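The tests with DESeq2, the newer edgeR fit, the thalamic covariate, fry and annotation-based lncRNA types were chosen after the data were seen; limma on FPKM was the test first written. Genes called in tMCAO against sham numbered 0, and 2 with pseudocount 0.1 in limma, 14 with voom library weights, 29 with only the 2 groups compared, 836 with DESeq2, 2 with the newer edgeR fit, and 0 to 91 leaving out 1 library. For celastrol against tMCAO they numbered 0, and 18 with DESeq2 and 0 to 2 leaving out 1 library. For celastrol against sham they numbered 1, and 3 with pseudocount 0.1, 3 with no filter, 2 with an FPKM of at least 1, 3 with quantile normalization, 8 with voom weights, 4 with only the 2 groups compared, 380 with DESeq2, 6 with the newer edgeR fit, 0 with the thalamic covariate, and 0 to 46 leaving out 1 library. With pseudocount 1 or limma on FPKM the 1 gene was Lcn2, not Fcgr4 (adjusted p = 0.0955 and 0.0515). LncRNA genes called in tMCAO against sham numbered 0, and 47 with DESeq2 and 0 to 2 leaving out 1 library; in celastrol against tMCAO they numbered 0 under all 24 alternatives. Opposite calls numbered 0, and 12 with DESeq2 and 0 to 2 leaving out 1 library. Gene lists called in tMCAO against sham numbered 26, and 0 with an estimated correlation, 6 with fry and 25 to 31 leaving out 1 library. In celastrol against tMCAO they numbered 22, and 0 with an estimated correlation, 0 with fry and 14 to 24 leaving out 1 library. The estimated correlation and fry count the correlation between list members. Celastrol replicate 2 and the thalamic covariate are taken up below, and for the other differences the cause was not tested.

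The labels do not say that the replicate numbers pair the libraries. Deviations from the group means correlated at −0.156 to 0.198 between same-numbered libraries. Between differently numbered libraries of different groups they correlated at −0.264 to 0.227. With 3 libraries per group these values cannot settle whether the numbers mark a pairing or a batch. With the replicate block 51 genes were called in tMCAO against sham, 0 in celastrol against tMCAO and 22 in celastrol against sham. Of the values of named genes under the alternatives, 1836 of 2016 in tMCAO against sham, 1082 of 1098 in celastrol against tMCAO and 586 of 665 in celastrol against sham kept their direction and side of the threshold. Most of these genes were chosen by smallest p in the same libraries, which favours a kept direction. In tMCAO against sham and celastrol against tMCAO none passed, so a kept side of the threshold means still not passing. The hypothalamic gene Agrp was at −1.98 (log2) in celastrol against tMCAO and turned to 0.086 without tMCAO replicate 1, with values from −2.50 to 0.086 leaving out 1 library; the cause was not tested. Genes near 3 counts in a library are limited by depth, and no alternative moved the median of all genes by over 0.098 (log2).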

Other observations

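Tests of replicate 2 of the celastrol group, of the erythrocyte genes, of the thalamic covariate and of the spread were chosen only after the results were seen; the counts of splits were planned.

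Brain regions and fluid barriers differed between libraries of a group. The choroid plexus gene Ttr, which encodes the thyroxine carrier transthyretin, was at 1656 CPM in celastrol replicate 1, 398 in replicate 3 and 3.52 in replicate 2. In tMCAO it was at 239, 453 and 1.39 CPM in replicates 1, 2 and 3, and in sham at 22.0, 2.78 and 31.0 CPM. The hypothalamic peptide genes Pomc and Oxt were at 14.1 and 12.5 CPM in tMCAO replicate 1 and at or below 1.201 and 0.432 CPM in the other 8 libraries. Striatal scores were 1.31 in sham replicate 3 and 0.67 in tMCAO replicate 3, and negative in the other 7. Thalamic scores were 0.71, 2.06 and 1.56 in sham replicate 1, tMCAO replicate 2 and celastrol replicate 3, and negative in the other 6; hippocampal scores were 1.34, 1.83 and 1.75 in the same libraries.

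The 18 genes that DESeq2 called in celastrol against tMCAO, none of which passed edgeR's test over all genes, include Cx3cl1, Fam102b, Slc26a10, Cirbp, Lhx2, Prelp and the globin gene Hbb-bt. DESeq2 called 12 of them in tMCAO against sham with the opposite sign, 3 that were higher after tMCAO and 9 that were lower. The same tMCAO libraries stand in both comparisons, which favours opposite signs.

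Celastrol replicate 2 had lower injury scores than the other celastrol libraries. A sham library under a celastrol label is argued against, since its neutrophil score was 3.334 and the highest in sham 0.847. Mixing with uninjured tissue at 1 share would leave every list a similar share of its excess above sham, relative to the other celastrol libraries. Of the lists compared, the median over members was highest for endothelial activation genes (86.2%, quartiles 41.0% to 112%). Complement (72.9%, 30.4% to 108%) and neutrophil markers (36.5%, 29.5% to 45.3%) followed. Matrix remodelling genes were lowest (6.9%, quartiles −10.2% to 16.9%), with cytokines at 10.2%, NRF2 genes at 12%, activated microglia at 15.1% and reactive astrocyte genes at 17.6%. The unequal shares argue against mixing at 1 share for all lists, but the low ones were alike, and genes of 1 library are not replicates. A smaller or differently placed lesion, or a different response to the drug, stays open and was not tested. Splits of celastrol against sham gave 2049 genes at an unadjusted p under 0.05 where sham replicates 2 and 3 were grouped with celastrol replicate 2, against 1445 for the real split, which points to a structure of the samples.

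Erythrocyte genes were lower in the celastrol group. One hypothesis is that these hemispheres held less blood: summed over genes, non-globin erythrocyte genes kept 26.58% of their tMCAO level and globin genes 27.73%, or 48.46% and 46.17% without tMCAO replicate 3, which is consistent with a loss of whole erythrocyte RNA. Lower globin in brain cells with equal blood stays open, since 1 gene, Alas2, made up 5.16 of the 5.32 CPM of the non-globin sum after tMCAO, and its change of −2.01 ± 0.66 (log2, SE) was −1.10 ± 0.55 without tMCAO replicate 3. Erythrocyte scores were at or below −1.49 in the celastrol libraries, but tMCAO replicate 2 was at −1.36. Whether perfusion, dissection or the drug set the blood content was not tested.

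No gene passed in tMCAO against sham although list members moved by several-fold. A candidate explanation is that celastrol replicate 2 widened the shared estimate of the spread: 91 genes were called without it, against at most 13 without any other library. Fewer than 91 were called with only the sham and tMCAO libraries in the fit, which drops all celastrol libraries. DESeq2 called 836 with all 9 libraries kept, so the 0 calls also depend on the test. Whether thalamic content that differs between libraries adds to the 0 calls was not decided. With the thalamic score, centred within each group, as a covariate, 0 genes were called, as without it. Genes at an unadjusted edgeR p under 0.05 numbered 2568 with the covariate and 2534 without. The covariate and the loss of a library each cost 1 degree of freedom, so 0 calls can come from lost power. What sets celastrol replicate 2 apart stays open.

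Splits of 3 against 3 libraries number 10, too few for a share under 0.05, and where the real count is 0 every split has as many by construction. As many genes or more were called in 10 of 10 splits for tMCAO against sham (real 0, highest other 5), 10 for celastrol against tMCAO (0; 2) and 5 for celastrol against sham (1; 3), and for lncRNAs in 10 of 10 for tMCAO against sham and for celastrol against tMCAO (0; 0). At an unadjusted p under 0.05 the number of splits with as many was 1 for tMCAO against sham (2534; 1530), 8 for celastrol against tMCAO (698; 1827) and 2 for celastrol against sham (1445; 2049). The split with 1827 sets tMCAO replicate 2 with celastrol replicates 2 and 3 and points to a structure of the samples other than the groups. For lists called by camera with the preset correlation it was 3 (26; 28), 4 (22; 30) and 4 (26; 30) in the same order. Of 20 assignments, 20 gave as many opposite calls (0; 2), again fixed by the 0.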
